A study of Mus musculus with 24 samples.

How the data were processed

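Bone marrow of C57BL/6 mice was sorted by flow cytometry into 4 populations: long-term hematopoietic stem cells (LT-HSC), short-term hematopoietic stem cells (ST-HSC), multipotent progenitors (MPP) and lineage-positive cells (Lin). Each was taken from animals given phosphate-buffered saline (PBS), which the labels also call untreated, or polyinosinic:polycytidylic acid (pIpC), a synthetic double-stranded RNA that triggers type I interferon and drives HSC into division. The study's title asks about Primpol and repriming in HSC that divide under stress. With 3 replicates in each of 8 groups there were 24 libraries, and none was left out. The labels give no dose, time after injection, sort gate, sex or age, and do not say whether a replicate is an animal or a pool, so the origin of the replicates is unknown. Total RNA was extracted on columns with DNase treatment and sequenced with Illumina library preparation.

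Per the submitters' processing notes, reads were aligned with STAR and counted with featureCounts on GRCm38.p6. Versions, annotation release and strand setting are not given. The deposited files hold counts, whole numbers of reads per Ensembl gene without normalization by the authors, for 25746 genes per library. Of these 25712 were matched to GENCODE release M21. The 34 without a symbol took 0.011 to 0.046% of counts. Since the strand setting is unknown, values of genes that overlap another gene, of antisense genes and of close paralogs are less certain. Totals ran from 13178899 to 54891041 counts per library. A group with 0 counts of a gene was set to a floor of 3 counts over the group, and a fold against it is a lower bound. A group with 1 to 3 counts is given as a ratio with its exact 95% counting interval. No molecular identifiers are named in the labels, so intervals and floors cover counting error alone.

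Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 over the 8 groups, which left 15529 genes holding 99.98% of counts. Libraries were scaled by TMM and dispersions were estimated robustly (common biological coefficient of variation 0.468). A quasi-likelihood model with 1 mean per group was then fitted (16 residual degrees of freedom per gene, median 22.0 after moderation). All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes of each comparison, with a threshold of 0.05. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so calls rest on the spread shared across genes. The comparisons, fixed before the data were examined, were pIpC against PBS in each of the 4 cell types, their average, the difference of the pIpC effect between each of 3 cell types and LT-HSC, and each of those 3 cell types against LT-HSC after PBS. Counts scaled to 1e6 per library (CPM) use TMM-scaled library sizes.

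Before the data were examined, 36 gene lists with 815 symbols were written from general knowledge, of which 3 symbols had no gene in the files. Each list with at least 5 tested members was compared with the other genes by camera in limma 3.58.1 with a preset correlation of 0.01. It was compared again with a correlation estimated per list and tested on its own with fry. The preset test is the one described as higher or lower. It called 19, 12, 20 and 12 lists for pIpC in LT-HSC, ST-HSC, MPP and Lin, of which 1, 0, 0 and 2 held with an estimated correlation. Lists share genes and are not independent. Genes reported by name follow a rule written in advance. Among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries, these were the 8 largest changes in each direction (4 for differences of effect; for these and for the average, overlap was not asked), leaving out predicted models, pseudogenes and receptor segments. Added were 23 fixed genes in every pIpC comparison, among them Primpol, Ly6a, Kit, Cd48, Procr, Mki67, Myc, Irf7 and Rad18, and from each list described up to 4 members past the threshold with the smallest p, or the most abundant if none passed. Some genes that the rule selects are not reported here. By chance 10% of genes would have no overlap between 3 and 3 libraries.

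The series design counts 8 samples per replicate number, so numbers could mark a shared day or animals. In residuals from the group means, libraries of equal number correlated above 0.1 for all 3 numbers in 8 of 28 pairs of groups. Among these were PBS and pIpC of MPP (r = 0.356, 0.201 and 0.241) and of Lin (0.366, 0.288 and 0.214). They were not all above it for LT-HSC (0.292, 0.0347 and 0.184) or ST-HSC (0.325, 0.0933 and 0.393). Of 24 libraries 22 correlated best with their own number. These correlations are across genes, which are not independent. The value with replicate number as a block is therefore given beside the MPP result.

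The fit was tested on simulated data with 200 changed genes among 15529. At 4-fold it recovered 61, 66, 64 and 73 of 100 genes for pIpC in LT-HSC, ST-HSC, MPP and Lin. At 2-fold it was 14, 13, 12 and 8. False calls were 1, 4, 2 and 5, but may differ where libraries correlate by number. With so few changed genes, single changes of 2-fold or less would mostly be missed at this spread. In LT-HSC, where 6190 genes passed, some changes near 2-fold did pass.

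Alternatives were size factors of the DESeq2 type, no filter, a filter of 5 CPM in 3 libraries, and the replicate number as a block (also within treatment). Others were glmTreat against a fold of 1.5, the DESeq2 1.42.0 Wald test, limma voom with sample weights, a fit of only the libraries compared, and each library left out. Further alternatives were chosen after seeing the data: replicate numbers 1 and 2 only, offsets for GC content and exon length (mgcv 1.9.3), the share of counts on TEC gene models as a covariate, and protein-coding genes over 5 CPM. Groups were also split in other ways to count how often a split calls as many genes: all 10 splits of 3 against 3, or 100 drawn splits. Not used here were any published lists from the study.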

Results

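Expression of 15529 genes was compared in bone marrow cells taken after pIpC or PBS, with 3 libraries in each of 8 groups. Each gene is given as a log2 fold change ± standard error with its adjusted p, or as a mean of counts scaled to 1e6 per library (CPM) ± SD of 3 libraries.

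Long-term hematopoietic stem cells (LT-HSC), the self-renewing cells at the top of the blood hierarchy, had the most changed genes: 6190 passed the threshold after pIpC, 2740 higher and 3450 lower. As this was 39.9% of all genes tested, counts within lists in LT-HSC are to be read against that share. Transcripts that mark LT-HSC fell together. Hlf, a transcription factor that guards stem cell dormancy, fell from 244 ± 22.6 to 12.5 ± 4.83 CPM (-4.29 ± 0.32, adjusted p = 2.37e-08). Procr, the endothelial protein C receptor used to isolate HSC, fell from 91.6 ± 30.5 to 5.03 ± 1.14 CPM (-4.19 ± 0.60, 2.70e-05). The cytokine gene Ltb changed by -4.02 ± 0.40, the guidance receptor Robo4 by -4.32 ± 0.43 and the sulfotransferase Sult1a1 by -4.44 ± 0.48. The cyclin-dependent kinase inhibitor Cdkn1c (p57), needed for HSC quiescence, went from 15.8 ± 10.6 to 0.860 ± 0.489 CPM (-4.20 ± 1.10, 0.00516). Of the 28 tested genes of the LT-HSC identity list, 23 were lower and none higher, and 24 were lower when adjusted over the list alone (median -2.54). That was the single list call in this comparison that held with an estimated correlation (adjusted p = 0.0176). Quiescence regulators were lower for 14 of 25 genes, with the same number adjusted over the list alone (median -1.25), among them Rgs1 (-2.49 ± 0.30) and the mRNA-decay factor Zfp36 (-3.37 ± 0.46). Its adjusted p was 0.257 with an estimated correlation. The platelet-lineage genes Itgb3 (-2.73 ± 0.39) and Vwf (-2.69 ± 0.47) fell as well; their list was lower with a preset correlation but had adjusted p = 0.269 with an estimated correlation.

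Genes of the cell cycle and of DNA replication rose in the same LT-HSC. Cd48, a surface receptor absent from the most dormant HSC, went from 12.3 ± 3.11 to 135 ± 19.0 CPM (3.46 ± 0.39, adjusted p = 1.92e-06). The mitotic kinases Plk1 (3.06 ± 0.39), Aurkb (2.49 ± 0.30) and Ttk (2.47 ± 0.31) rose. Of 32 mitosis genes 30 were higher, 31 when adjusted over the list alone (median 2.10; adjusted p = 0.229 with an estimated correlation). Replication origins fire through the MCM helicase: Mcm5 rose from 136 ± 25.1 to 528 ± 68.2 CPM (1.96 ± 0.39, 5.64e-04), with Mcm10 (2.43 ± 0.37), Cdc45 (2.36 ± 0.36), Cdc6 (2.07 ± 0.32) and the kinase subunit Dbf4 (1.97 ± 0.29). Licensing and firing genes were higher for 22 of 27, or 23 adjusted over the list alone. Elongation genes, such as Rrm2 (2.97 ± 0.38) and Top2a (1.86 ± 0.30), were higher for 26 of 35, or 28 adjusted over the list alone. Each call had adjusted p = 0.257 with an estimated correlation. The fork-repair genes Fanci (1.49 ± 0.22) and Wrn (1.39 ± 0.23) rose, as did 20 of 36 genes of that list (21 adjusted over the list alone, adjusted p = 0.257 with an estimated correlation). The checkpoint kinase Chek1 (1.25 ± 0.34), the phosphatase Cdc25c (1.89 ± 0.28) and the clamp subunit Rad9a (1.02 ± 0.21) were higher too. Myc rose from 219.7 ± 78.6 to 756 ± 44.1 CPM (1.78 ± 0.34, 4.31e-04). Ribosome biogenesis genes were higher for 27 of 28, the same number adjusted over the list alone, among them Rrp9 (1.98 ± 0.22) and Nop2 (1.92 ± 0.27), with adjusted p = 0.257 with an estimated correlation.

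Some DNA-damage tolerance genes, which copy past lesions or restart stalled forks, changed, but no larger a share than of all genes. Rad18, the ubiquitin ligase that opens translesion synthesis, rose from 40.6 ± 2.27 to 102 ± 8.53 CPM (1.33 ± 0.24, adjusted p = 2.88e-04), with Rfwd3 (1.30 ± 0.25), Ube2a (0.96 ± 0.21) and Usp1 (1.20 ± 0.32). Of 23 genes in the repriming and translesion list 7 were higher and 2 lower, while 39.9% of all genes tested passed. The list as a whole did not pass (median 0.53, adjusted p = 0.0542, or 0.401 with an estimated correlation). Primpol, the primase-polymerase that restarts synthesis ahead of a lesion (ENSMUSG00000038225, GRCm38 chromosome 8, 46575594 to 46617212), was not shown to change in any cell type. Its CPM went from 33.3 ± 4.59 to 31.3 ± 0.958 in LT-HSC (-0.089 ± 0.21, 95% interval -0.53 to 0.35, adjusted p = 0.767). In short-term HSC it went from 34.5 ± 5.52 to 32.5 ± 2.91 (-0.086 ± 0.21, interval -0.53 to 0.36, 0.851). In multipotent progenitors Primpol went from 37.0 ± 10.3 to 30.1 ± 2.11 CPM (-0.30 ± 0.21, interval -0.74 to 0.15, 0.452) and in lineage-positive cells from 40.3 ± 6.49 to 38.1 ± 3.79 CPM (-0.080 ± 0.21, interval -0.52 to 0.36, 0.999). The pIpC effect on Primpol relative to LT-HSC differed by 0.0032 ± 0.30 in ST-HSC, -0.21 ± 0.30 in MPP and 0.0085 ± 0.30 in Lin, with adjusted p = 1.0, 0.795 and 1.0.

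Interferon-related genes moved in both directions in LT-HSC. Irf7, the master regulator of interferon production, rose from 35.5 ± 7.09 to 102 ± 6.93 CPM (1.51 ± 0.38, adjusted p = 0.00365). Ly6a (Sca-1), a stem cell marker that interferon induces, fell from 99.4 ± 30.9 to 23.9 ± 4.08 CPM (-2.06 ± 0.31, 4.68e-05). Stat2 (-1.29 ± 0.28), the RNA sensor Ddx58 (-1.18 ± 0.27), Slfn5 (-2.48 ± 0.56) and the receptor subunit Ifnar1 (-1.29 ± 0.28) also fell. Among 51 type I interferon-stimulated genes 5 were higher and 13 lower, and the list did not pass (median -0.25, adjusted p = 0.407). Interferon-inducible GTPases and interferon gamma targets were lower for 16 of 24, the same number adjusted over the list alone, including Gbp8 (-3.66 ± 0.49) and the myeloid factor Irf8 (-2.90 ± 0.32), with adjusted p = 0.257 with an estimated correlation. MHC class II genes, among them H2-Aa (-3.76 ± 0.48) and the invariant chain Cd74 (-3.81 ± 0.58), were lower for 7 of 10, or 8 adjusted over the list alone (adjusted p = 0.261 with an estimated correlation). The inflammatory genes Icam1 (-2.41 ± 0.25) and Ccl4 (-5.71 ± 0.59) and the priming genes Csf3r (-3.74 ± 0.48) and Flt3 (-2.70 ± 0.45) fell. Cd34 (-2.05 ± 0.64, 0.0152) and Ccnd1 (-1.42 ± 0.53, 0.0386) were lower, and Mki67 (1.29 ± 0.36), Cdk6 (1.56 ± 0.33) and Cdkn1a (1.14 ± 0.43, 0.0395) higher. Kit, Slamf1, Ifit1 and Rev1 did not pass, with adjusted p from 0.0601 for Kit to 0.616 for Slamf1.

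Some erythroid genes rose in LT-HSC. Carbonic anhydrase Car1 went from 214 ± 127 to 3979 ± 1098 CPM (4.21 ± 0.75, adjusted p = 2.54e-04). The erythroid factor Klf1 rose from 41.0 ± 13.9 to 531 ± 45.5 CPM (3.70 ± 0.85, 0.00240), with Ermap (3.43 ± 0.94) and the erythropoietin receptor Epor (2.52 ± 0.71). Of 21 erythroid genes 8 were higher, 9 adjusted over the list alone, with adjusted p = 0.730 with an estimated correlation. The membrane protein Susd2 was at least 400.0-fold higher, from 0 counts to 10.4 ± 5.21 CPM, and the GTPase Rem2 rose to 5.33 ± 0.864 CPM (189.8-fold, counting interval 64.7 to 922). Scin, an actin-severing protein, rose to 64.1 ± 15.7 CPM (7.23 ± 1.42), and Add2, an adducin of the red cell skeleton, to 61.0 ± 15.2 CPM (6.02 ± 1.22). Gstp3 (7.15 ± 0.98), the channel subunit Kcng2 (7.11 ± 1.18), the IgE receptor chain Ms4a2 (6.89 ± 0.86) and Ccdc180 (6.26 ± 0.84) rose from under 1 CPM. Unc45b, a myosin chaperone, fell from 28.3 ± 1.74 to 0.404 ± 0.202 CPM (-6.12 ± 0.66, 4.10e-06). So did the retinoic acid hydroxylase Cyp26b1 (-7.29 ± 1.18), the dendritic cell receptor Clec9a (-7.19 ± 1.67), Nsun7 (-7.14 ± 1.11), Pbld1 (-6.54 ± 1.73), Plekhg1 (-6.09 ± 0.79) and Mmp16 (-5.90 ± 1.14). The phosphatase Dusp26 went from 5.21 ± 3.13 CPM to 2 counts (329-fold, counting interval 90.5 to 2721).

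Energy genes split by genome in LT-HSC. Nuclear oxidative phosphorylation genes were higher for 27 of 36 (the same number adjusted over the list alone), with Cycs (2.21 ± 0.24) and Cyc1 (1.61 ± 0.23). Ribosomal protein genes were higher for 12 of 47 (8 adjusted over the list alone), with Rps2 (1.38 ± 0.32). These list calls had adjusted p = 0.257 and 0.730 with an estimated correlation. With the TEC share (below) as a covariate the oxidative phosphorylation median went from 1.07 to 0.61. The ribosomal protein median went from 0.64 to 0.24, and that call was lost (adjusted p = 0.0860). Among 10000 random lists matched on abundance, the median of 0.64 lay at percentile 67.8 and that of 1.07 at 99.9. The mitochondrially encoded mt-Nd6 fell from 358 ± 114 to 60.9 ± 18.7 CPM (-2.56 ± 0.56), and 6 of 12 such genes were lower (median -1.66; adjusted p = 0.559 with an estimated correlation). Mitochondrial transcripts took 1.97 to 3.67% of counts in the PBS libraries and 0.661 to 0.818% after pIpC. Counts on TEC gene models, an annotation class of loci of unproven status, took 0.456 to 2.28% after PBS, and 243 of 1234 such models were lower after pIpC against 42 higher. With that share as a covariate the call of the mitochondrially encoded list was lost too (adjusted p = 0.262). Without LT-HSC pIpC replicate 1 the count of changed genes was 4112 in place of 6190. Of 76 genes named here that passed, 73 passed with each of the 6 libraries left out in turn. Cdkn1a missed the threshold without PBS replicate 3 (adjusted p = 0.146), Cdkn1a and Ccnd1 without PBS replicate 1 (highest 0.370) or pIpC replicate 2 (highest 0.105), and both with Cd34 without pIpC replicate 1 (highest 0.134) or 3 (highest 0.119). The erythroid and platelet-lineage list calls were lost without PBS replicate 1 (adjusted p = 0.0757 and 0.0554), and the erythroid call with the replicate block and the stricter filter as well.

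**Figure D1:**
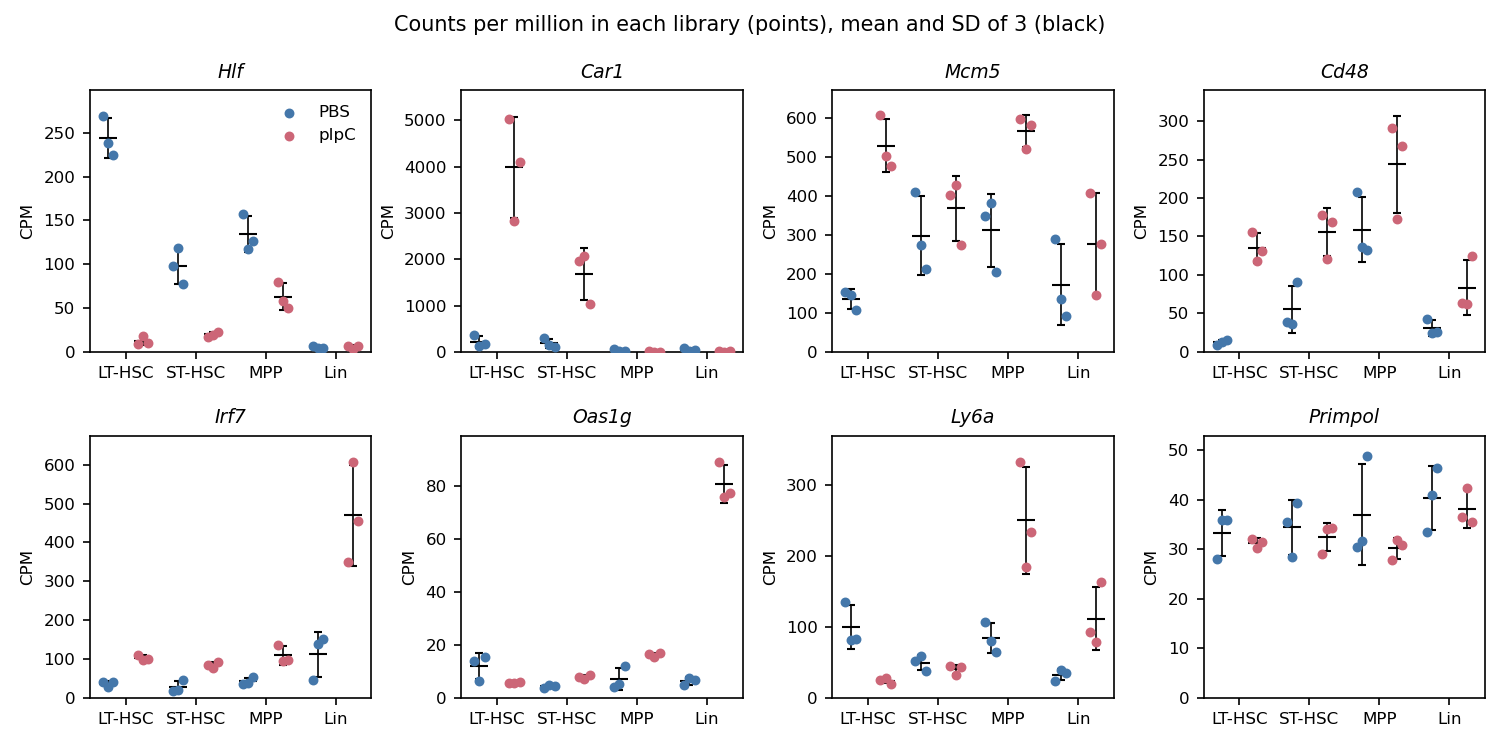
CPM of 8 genes in each library, by cell type and treatment; points are libraries and black marks the mean ± SD of 3 libraries. Hlf fell and Cd48, Mcm5 and Car1 rose in LT-HSC after pIpC, Oas1g rose in Lin, and Primpol stayed between 27.8 and 48.9 CPM.

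Short-term HSC (ST-HSC), which sustain blood for weeks rather than for life, changed in 316 genes after pIpC, 106 higher and 210 lower. Stem cell markers that fell in LT-HSC fell here too: Hlf went from 98.1 ± 20.5 to 19.8 ± 2.46 CPM (-2.31 ± 0.30, adjusted p = 3.97e-04). Procr went from 25.7 ± 3.45 to 5.33 ± 1.15 CPM (-2.27 ± 0.56, 0.0338) and Robo4 from 18.8 ± 1.46 to 3.08 ± 0.251 CPM (-2.61 ± 0.41, 0.00246). Sult1a1 (-2.62 ± 0.45) and Ltb (-2.01 ± 0.37) fell too, so that 9 of 28 identity genes were lower, 13 adjusted over the list alone (median -1.12; adjusted p = 0.0590 with an estimated correlation). Alcam, a cell adhesion molecule, fell from 15.4 ± 4.95 to 1.60 ± 0.471 CPM (-3.27 ± 0.32, 1.22e-05). It fell along with the zinc finger gene Zfp618 (-3.83 ± 0.98), the GTPase regulator Sgsm1 (-3.80 ± 0.67), Hid1 (-3.24 ± 0.60), the nuclear envelope protein Syne2 (-3.24 ± 0.58), the cytokine Clcf1 (-3.19 ± 0.66), tensin Tns2 (-3.15 ± 0.64) and the receptor Npr2 (-3.12 ± 0.80). Metallothioneins, which bind zinc, rose: Mt1 from 19.6 ± 6.94 to 158 ± 44.5 CPM (3.02 ± 0.50, 0.00356) and Mt2 from 2.03 ± 0.555 to 29.8 ± 11.8 CPM (3.87 ± 0.81, 0.0129). Car1 rose from 184 ± 100.4 to 1687 ± 564 CPM (3.19 ± 0.72, 0.0210), with Ccdc180 (4.43 ± 0.75), the chemokine receptor Cx3cr1 (4.12 ± 0.88), the chemokine Ccl5 (3.37 ± 0.71), Trib2 (3.17 ± 0.66) and Dapk2 (3.58 ± 0.94). Eosinophil, basophil and mast cell genes were higher as a list (median 1.39, or 0.87 with genes at 0 set to their bound; adjusted p = 0.233 with an estimated correlation), with Siglecf (1.96 ± 0.30) and Ms4a2 (2.80 ± 0.64) passing.

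Interferon-stimulated genes rose in part in ST-HSC. Irf7 went from 26.4 ± 15.8 to 84.0 ± 8.17 CPM (1.67 ± 0.38, adjusted p = 0.0217) and the nucleotide kinase Cmpk2 from 26.4 ± 7.95 to 74.5 ± 17.8 CPM (1.5 ± 0.33, 0.0176); these were the 2 of 51 that passed, and the same number adjusted over the list alone (median 0.23; adjusted p = 0.635 with an estimated correlation). Cd48 rose (1.5 ± 0.36, 0.0286) and Flt3 fell (-1.76 ± 0.43, 0.0338). Cycs (1.10 ± 0.24) was the passing oxidative phosphorylation gene of 36 (3 adjusted over the list alone) and Rrp9 (0.87 ± 0.21) the passing ribosome biogenesis gene of 28 (11 adjusted over the list alone). Their lists were higher (medians 0.54 and 0.77), with adjusted p = 0.635 and 0.572 with an estimated correlation. None of 47 ribosomal protein genes passed, over all genes or adjusted over the list alone, while that list was higher (median 0.49; adjusted p = 0.677 with an estimated correlation). Among 10000 random lists matched on abundance, that median lay at percentile 86.8. Ly6a, Kit, Slamf1, Cd34, Mki67, Mcm5, Ccnd1, Cdk6, Cdkn1a, Cdkn1c, Myc, Ifit1, Ifnar1, Rev1, Rad18 and Chek1 did not pass; the smallest adjusted p among them was 0.103 for Myc. Neutrophil genes were higher as a list (median 4.16, or 4.08 with genes at 0 set to their bound; adjusted p = 0.764 with an estimated correlation). This rested on pIpC replicate 1, whose mean log2 CPM over the list was 5.51 against -1.82 to 1.18 in the other 5 libraries. Without it the list was lower (adjusted p = 0.0180), and without PBS replicate 2 or 3 it did not pass (0.196 and 0.0505). The call was also lost with the replicate block (0.108) and with the TEC share as a covariate (0.242). Padi4 itself fell (-1.55 ± 0.35).

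ST-HSC counts moved with single libraries: 175 genes passed without PBS replicate 2, 170.0 without PBS replicate 3, 94 without pIpC replicate 1 and 89 without pIpC replicate 2. The tool moved them the other way: DESeq2 called 477 higher and 810.0 lower and limma voom 997 and 1205, where edgeR called 106 and 210.0. The replicate block gave 1039 genes and the TEC covariate 522. Of 30 named genes that passed, 11 passed in each of the 6 such fits: Alcam, Ccdc180, Hid1, Mt1, Sgsm1, Syne2, Hlf, Robo4, Sult1a1, Ltb and Siglecf. Between 7 and 16 of the others missed the threshold in each fit: without PBS replicate 1, 2 or 3 the highest adjusted p was 0.0969, 0.153 and 0.123, and without pIpC replicate 1, 2 or 3 it was 0.213, 0.203 and 0.0912. Dapk2, Procr and Rrp9 missed it in all 6 fits.

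Multipotent progenitors (MPP), which feed the myeloid and lymphoid lineages, changed in 30 genes, 19 higher and 11 lower. Ms4a4c, a membrane protein that interferon induces, rose from 3.30 ± 1.85 to 57.5 ± 12.4 CPM (4.12 ± 0.63, adjusted p = 0.0120). The monocyte antigen Ly6c2 rose from 7.40 ± 1.53 to 120.4 ± 39.8 CPM (4.03 ± 0.77, 0.0459) and Ms4a3, a granulocyte-monocyte progenitor gene, from 9.26 ± 2.76 to 115 ± 39.7 CPM (3.63 ± 0.62, 0.0186). Irf8, which directs monocyte and dendritic fate, rose from 89.6 ± 18.0 to 288 ± 41.4 CPM (1.68 ± 0.29, 0.0186), and Ly6a from 83.5 ± 21.4 to 249.7 ± 75.8 CPM (1.58 ± 0.31, 0.0459). Complement C3 (4.08 ± 0.82), Igsf6 (3.41 ± 0.70), the claudin Cldn15 (3.25 ± 0.63), the DNA sensor family gene Ifi209 (3.24 ± 0.64), Ms4a6c (2.32 ± 0.43) and the vesicle adaptor Ap3s1 (2.96 ± 0.36, 4.89e-04) rose. The lymphocyte GTPase Gimap8 (-3.05 ± 0.62), the Polycomb partner Phf1 (-2.05 ± 0.42), plakoglobin Jup (-2.0 ± 0.41), Rgp1 (-1.72 ± 0.36), Dennd2d (-1.50 ± 0.31), Ttc39b (-1.47 ± 0.27) and Gprasp1 (-1.20 ± 0.24) fell. Of 51 interferon-stimulated genes 1 passed, Ly6a, and 11 adjusted over the list alone (median 0.61; adjusted p = 0.332 with an estimated correlation). Ribosome biogenesis, oxidative phosphorylation and glycolysis genes were higher as lists (medians 0.77, 0.55 and 0.82), with adjusted p = 0.332 for each with an estimated correlation. Mitochondrial transcripts took 1.20 to 3.43% of counts in MPP after PBS and 0.648 to 0.801% after pIpC, and TEC gene models 0.477 to 1.94% and 0.291 to 0.367%. With the TEC share as a covariate the oxidative phosphorylation median was 0.31. None of the genes of these 3 lists passed over all genes, against 11, 4 and 11 adjusted over the list alone. The abundant Npm1 (1.21 ± 0.32, 0.105), Eif5a (1.10 ± 0.32, 0.133) and Ldha (1.43 ± 0.34, 0.0737) did not pass. The identity list was lower (median -0.90; 5 lower and 1 higher adjusted over the list alone; adjusted p = 0.332 with an estimated correlation). So was the erythroid list (median -2.67; 1 lower adjusted over the list alone; adjusted p = 0.435 with an estimated correlation), with Car2 at -0.41 not passing.

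Other fixed genes named here did not pass in MPP: Kit, Slamf1, Cd48, Flt3, Procr, Cd34, Mki67, Mcm5, Ccnd1, Cdk6, Cdkn1a, Cdkn1c, Myc, Irf7, Ifit1, Ifnar1, Rev1, Rad18 and Chek1, with Irf7 closest (1.39 ± 0.38, adjusted p = 0.105). The MPP count depended on the fit. With the replicate number as a block, since numbers pair these libraries, 932 genes passed in place of 30, and DESeq2 called 276 higher and 449 lower where edgeR called 19 and 11. With limma voom 2487 genes passed, in a fit of only the libraries compared 447, with DESeq2-type size factors 18 and with no filter 13. Single libraries moved it as well: 2, 19 and 1 genes passed without PBS replicate 1, 2 and 3, and 10, 1 and 2 without pIpC replicate 1, 2 and 3. Of 18 named genes that passed, Ap3s1 alone passed in each of these fits. C3, Dennd2d, Ifi209, Igsf6, Jup, Ly6a and Ly6c2 missed the threshold without PBS replicate 2 (adjusted p = 0.070 to 0.0891). Without PBS replicate 1 or 3, or pIpC replicate 1, 2 or 3, 13 to 17 of the 18 missed it, with adjusted p up to 0.162, 0.312, 0.204, 0.237 and 0.316. The identity and interferon lists kept their calls with each library left out.

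Lineage-positive cells (Lin), the maturing blood cells, changed in 100 genes after pIpC, 92 higher and 8 lower. Oas1g, which makes the messenger that activates RNase L, rose from 6.27 ± 1.42 to 80.8 ± 7.29 CPM (3.68 ± 0.38, adjusted p = 1.96e-05). Irf7 rose from 111 ± 57.6 to 469.7 ± 130.1 CPM (2.08 ± 0.38, 0.00786) and the class I antigen-presenting gene H2-K1 from 1107 ± 211 to 5068 ± 841 CPM (2.19 ± 0.23, 1.96e-05). Of 51 interferon-stimulated genes 12 were higher and none lower, 28 adjusted over the list alone (median 1.12). They included Oas1a (2.06 ± 0.30), Lgals3bp (2.02 ± 0.31), Xaf1 (1.85 ± 0.31), Ifi27l2a (2.91 ± 0.62) and Ly6a (1.79 ± 0.31, 0.00422). MHC class I genes were higher for 6 of 21, 13 adjusted over the list alone, with H2-Q7 (2.64 ± 0.28), H2-Q6 (2.73 ± 0.31) and the peptide transporter Tap1 (1.40 ± 0.21). Both list calls held with an estimated correlation (adjusted p = 6.37e-04 for each). The interferon-inducible GTPases Gbp7 (1.0 ± 0.22) and Iigp1 (1.58 ± 0.37) rose, 2 of 24 of their list or 6 adjusted over the list alone (adjusted p = 0.107 with an estimated correlation). Some lymphoid genes rose too: the natural killer receptor Klrb1c from 1.75 ± 0.904 to 36.5 ± 27.3 CPM (4.38 ± 0.78, 0.00547). The T cell factor Gata3 rose from 1.64 ± 0.272 to 10.8 ± 5.79 CPM (2.72 ± 0.40, 0.00112), as did the granule protein Nkg7 (2.07 ± 0.46) and the kinase Lck (1.99 ± 0.45), 3 of 20 T and NK cell genes or 11 adjusted over the list alone (adjusted p = 0.103 with an estimated correlation). Complement factor Cfb (4.22 ± 0.92), Ctla2a (2.96 ± 0.46), protein S Pros1 (2.91 ± 0.57), Ms4a6c (2.10 ± 0.43) and Rrp9 (1.34 ± 0.23) also rose.

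The genes lower in Lin, the erythroid regulator Sox6 (-5.70 ± 1.08, adjusted p = 0.0124), Sphk1 (-3.25 ± 0.72), Ubac1 (-3.02 ± 0.66), Mgst3 (-2.78 ± 0.64) and Gclc (-2.47 ± 0.56), rested on PBS replicate 3. That library held 1.92% hemoglobin counts against 0.0119 and 0.00950% in the other PBS replicates, and without it the adjusted p were 0.111, 0.420, 0.714, 0.898 and 0.368. The erythroid list was lower (median -3.88), with none of 21 genes passing over all genes and all of them adjusted over the list alone. The mean log2 CPM over the list was 8.73 in PBS replicate 3, against 4.35 and 3.38 in PBS replicates 1 and 2 and 3.16, 2.07 and 4.88 after pIpC. The list call held with each library left out. It was lost with an estimated correlation (adjusted p = 0.143), and the abundant Hbb-bs (-3.95 ± 1.51, 0.356) did not pass. Ribosomal protein genes (median 0.31) and oxidative phosphorylation genes (median 0.25) were higher as lists, with no gene of either passing over all genes or adjusted over the list alone. Their adjusted p was 0.745 and 0.778 with an estimated correlation, and the calls were lost without PBS replicate 2 (0.890 and 0.285) and, for oxidative phosphorylation, without PBS replicate 3 (0.668). With the TEC share as a covariate the oxidative phosphorylation median was 0.15 and the call was lost (adjusted p = 0.0820). The fixed genes Kit, Slamf1, Cd48, Flt3, Procr, Cd34, Mki67, Mcm5, Ccnd1, Cdk6, Cdkn1a, Cdkn1c, Myc, Ifit1, Ifnar1, Rev1, Rad18 and Chek1 did not pass, with Myc (1.47 ± 0.35, 0.0507) and Cd48 (1.44 ± 0.36, 0.0674) closest. Without PBS replicate 1, 2 or pIpC replicate 3, 282, 166 and 55 genes passed in place of 100, and DESeq2 called 231 higher and 114 lower. With limma voom 48 genes passed and in a fit of only the libraries compared 4. Of 27 named genes that passed, 13 passed with each library left out: Ctla2a, Gata3, H2-Q6, Irf7, Ly6a, Oas1g, Oas1a, Lgals3bp, Xaf1, H2-K1, H2-Q7, Tap1 and Rrp9. The other 14 missed the threshold without pIpC replicate 3 (adjusted p up to 0.314). Of these 6 and 7 did without pIpC replicate 1 and 2 (up to 0.136 and 0.139), and 4, 4 and 10 without PBS replicate 1, 2 and 3 (up to 0.080, 0.148 and 0.898).

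**Figure D2:**
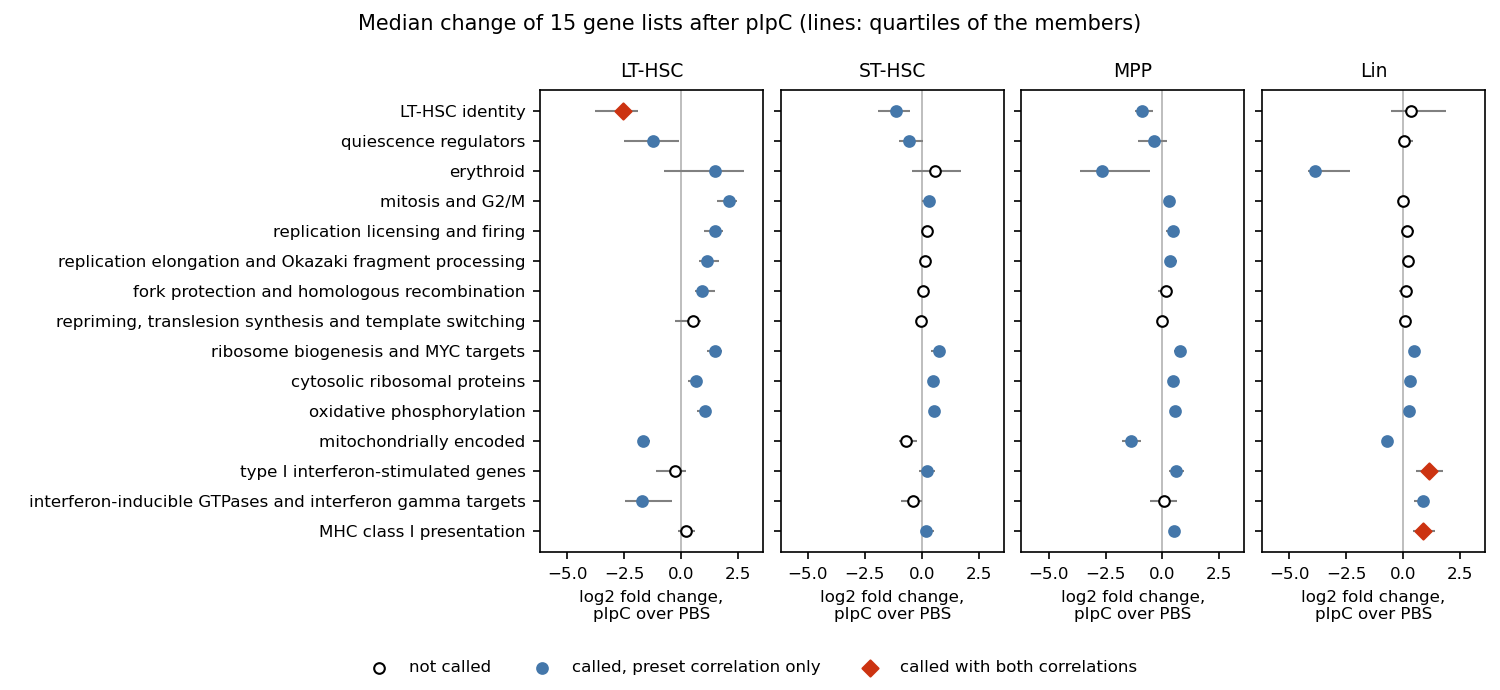
Median log2 fold change (pIpC against PBS) of 15 gene lists in 4 cell types; points are medians over list members and lines span their quartiles. Open points did not pass, blue circles passed with a preset correlation alone and red diamonds passed with an estimated correlation too: the identity list in LT-HSC and the interferon-stimulated and MHC class I lists in Lin.

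Averaged over the 4 cell types with equal weights, 6285 genes changed, 2978 higher and 3307 lower. The count followed the LT-HSC libraries all the same. Other splits that kept LT-HSC PBS and pIpC libraries apart reached up to 4608 genes, and those that mixed them at most 1. Cd48 (1.75 ± 0.18, adjusted p = 1.06e-06) and Irf7 (1.66 ± 0.19, 3.36e-06) rose, and Hlf fell (-1.90 ± 0.15, 5.12e-08) with Ltb (-1.81 ± 0.18). The mitotic kinases Plk1 (1.28 ± 0.18) and Aurkb (1.02 ± 0.15) and the ribosomal protein gene Rps2 (0.90 ± 0.16) were higher, and H2-Aa (-1.61 ± 0.22) and mt-Nd6 (-1.72 ± 0.27) lower. The largest fitted gains were Cd300e (5.32 ± 0.82), the NKG2D receptor Klrk1 (4.70 ± 0.59), Cd300ld (4.61 ± 1.57), Cldn15 (4.09 ± 0.71), Sirpb1a (3.66 ± 0.97), the chemokine Ccl8 (3.64 ± 0.64), the kinase Bmx (3.64 ± 0.83) and Ms4a4c (3.62 ± 0.38). Cd300e, Cd300ld and Sirpb1a had 0 counts in LT-HSC, ST-HSC and MPP after PBS, Klrk1 and Cldn15 in LT-HSC and ST-HSC, and Bmx in ST-HSC, so these values depend on the prior count. In ST-HSC after pIpC, Cd300ld, Sirpb1a and Bmx sat mostly in replicate 1 (2.71, 0.653 and 2.52 CPM). The largest fitted losses were Pkhd1l1 (-5.53 ± 0.91), Pbld1 (-4.82 ± 0.90), Xkr6 (-4.13 ± 0.98), Cldn5 (-3.69 ± 0.86), Fn3k (-3.58 ± 0.73), Fam131a (-3.54 ± 0.67), Myo5c (-3.52 ± 0.57) and Zfp612 (-3.49 ± 0.74). Of these Pkhd1l1, Pbld1, Xkr6, Cldn5, Fam131a and Myo5c had 0 counts in Lin after pIpC, with the same dependence. Ribosome biogenesis genes were higher for 26 of 28, as many adjusted over the list alone, with Rrp9 (1.17 ± 0.11) and Nop2 (1.07 ± 0.13). Oxidative phosphorylation genes were higher for 31 of 36, 34 adjusted over the list alone, with Cycs (1.16 ± 0.12) and Cyc1 (0.87 ± 0.11); adjusted p = 0.222 and 0.368 with an estimated correlation. MHC class I genes such as H2-Q7 (1.20 ± 0.13) and Tap1 (0.83 ± 0.10) rose for 14 of 21, 14 adjusted over the list alone. Interferon-stimulated genes such as Oas1a (1.07 ± 0.15) rose for 22 of 51, 23 adjusted over the list alone (adjusted p = 0.324 and 0.368 with an estimated correlation). Leaving out replicate 2 or 3 of every group gave 3786 and 2836 changed genes, and the TEC covariate 2582. Of 32 named genes that passed, 25 passed in each such fit. Pbld1, Sirpb1a and Xkr6 missed the threshold without replicate 1 (adjusted p = 0.0974 to 1.0), and Cd300ld, Cldn5, Myo5c, Sirpb1a, Xkr6 and Zfp612 without replicate 3 (0.0592 to 1.0).

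The pIpC effect differed between ST-HSC and LT-HSC for 123 genes, 64 with a more positive and 59 with a more negative effect in ST-HSC. Cell-cycle genes responded less in ST-HSC: the G1/S cyclin Ccne1 went from 3.65 to 71.5 CPM in LT-HSC and from 19.7 to 31.3 in ST-HSC (difference -3.61 ± 0.57, adjusted p = 0.00701). The checkpoint kinase Bub1 went from 6.13 to 68.5 and from 56.1 to 76.0 (-3.03 ± 0.60, 0.0232). Ttk (-2.54 ± 0.42), Kif4 (-2.12 ± 0.38), Ect2 (-2.64 ± 0.53) and Dbf4 (-1.84 ± 0.39) had lower effects in ST-HSC too. Of 32 mitosis genes 8 had a lower effect in ST-HSC, 30 adjusted over the list alone (median -1.64). The mean log2 CPM over this list was 4.365 to 4.813 in LT-HSC after PBS and 6.463 to 6.745 after pIpC. In ST-HSC it was already 6.68 to 7.109 after PBS, and 7.05 to 7.209 after pIpC. Whether the starting level accounts for the difference of effect was not tested. Hlf fell less in ST-HSC (1.98 ± 0.41, 0.0272). The mitosis and identity lists differed with an estimated correlation as well (adjusted p = 0.0349 for both). Replication licensing differed by the preset test (median -1.33, 1 of 27 genes lower, 19 adjusted over the list alone). So did elongation (median -0.98; 3 of 35, 13 alone) and repriming (median -0.42, no gene passing either way), with adjusted p = 0.0878, 0.0995 and 0.253 with an estimated correlation. Irf8 had a higher effect in ST-HSC (2.83 ± 0.43, 0.00462). The adaptor Dok3 (3.97 ± 0.65), Mgst2 (4.47 ± 0.84), cadherin Cdh23 (4.15 ± 0.99) and the myeloid lectin Cd33 (9.45 ± 1.64) had a more positive effect in ST-HSC, and Hexim2 (-3.96 ± 0.89) and Gstp3 (-5.81 ± 1.15) a more negative one. Cd33 was at 2.92 ± 4.51 CPM in ST-HSC after pIpC, mostly from replicate 1, the library with high neutrophil genes. None of the fixed genes named here passed; Ly6a (1.75 ± 0.43, 0.0563) and Cd48 (-1.96 ± 0.50, 0.0657) came closest, and the highest adjusted p was 1.0. The replicate block gave 371 genes in place of 123, the block within treatment 526, DESeq2 694, limma voom 234 and the TEC covariate 332. Without LT-HSC PBS replicate 2 or pIpC replicate 1, 2 or 3, 200, 17, 193 and 22 genes differed; without ST-HSC PBS replicate 1 or 2, 79 and 60.0; and without ST-HSC pIpC replicate 1, 2 or 3, 24, 77 and 34. Ccne1, Dok3, Irf8, Ttk and Kif4, of 14 named genes that passed, did so with each library left out. The others missed the threshold in fits without LT-HSC PBS replicate 1 or 3 (adjusted p up to 0.0559 and 0.0846), LT-HSC pIpC replicate 1, 2 or 3 (0.139, 0.0548 and 0.164), ST-HSC PBS replicate 1, 2 or 3 (0.0726, 0.0671 and 0.0775) or ST-HSC pIpC replicate 1, 2 or 3 (0.129, 0.0753 and 0.107).

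Between MPP and LT-HSC the pIpC effect differed for 1046 genes, 718 more positive and 328 more negative in MPP. Ly6a rose in MPP and fell in LT-HSC (difference 3.64 ± 0.44, adjusted p = 4.64e-05), Irf8 did the same (4.58 ± 0.43, 2.95e-06), and Cd48 responded less in MPP (-2.84 ± 0.51, 0.00130). Flt3 (2.33 ± 0.60), Procr (3.10 ± 0.77), Hlf (3.19 ± 0.41) and Sult1a1 (4.12 ± 0.64) had a more positive effect in MPP. Ccnd1 went from 20.6 to 46.2 CPM in MPP and from 25.75 to 9.66 in LT-HSC (difference 2.58 ± 0.75, 0.0400). Mki67 had a more negative effect (-1.76 ± 0.50, 0.0353). Ttk (-2.40 ± 0.42) and the centromere histone Cenpa (-2.08 ± 0.38) were among 24 of 32 mitosis genes with a lower effect, 30 adjusted over the list alone (adjusted p = 0.0585 with an estimated correlation). The mean log2 CPM over this list after PBS was 6.469 to 6.815 in MPP and 4.365 to 4.813 in LT-HSC. The identity list (11 of 28 genes, 15 adjusted over the list alone) and the multipotent priming list (8 of 20, 14 alone) held with an estimated correlation (adjusted p = 0.0378 and 0.0488). Interferon-stimulated genes such as Phf11d (3.08 ± 0.59), Oas1g (2.30 ± 0.49) and Ifitm3 (1.70 ± 0.39), and the GTPases Gbp9 (5.01 ± 0.91) and Gbp6 (4.02 ± 0.74), had a more positive effect in MPP. Gbp9 fell in LT-HSC (-4.21 ± 0.66) and stayed under 1 CPM in MPP, and Gbp6 fell in LT-HSC (-3.23 ± 0.54). A more positive effect was called for 8 of 51 and 12 of 24, or 12 and 15 adjusted over the list alone, with adjusted p = 0.301 and 0.0585 with an estimated correlation. Add2 went from 0.929 to 61.0 CPM in LT-HSC and from 1.92 to 0.335 in MPP (-8.54 ± 1.67). The collagen Col5a1 went from 0.875 to 43.7 and from 0.473 to 0.0786 (-7.99 ± 1.24). Trem3 went from 1.67 to 30.5 CPM in MPP and from 0.961 ± 1.592 to 0.106 in LT-HSC (difference 7.33 ± 1.76). Clec9a differed by 7.36 ± 2.12, and Smpdl3b, Btla and Susd2 had a group at 0 counts. Kit, Slamf1, Cd34, Mcm5, Cdk6, Cdkn1a, Cdkn1c, Myc, Irf7, Ifit1, Ifnar1, Rev1, Rad18 and Chek1 did not pass, with adjusted p from 0.0551 for Cdkn1c to 0.961 for Irf7. The block within treatment gave 1709 genes, DESeq2 1711, limma voom 2662 and the TEC covariate 1609. Counts fell to 562 and 535 without LT-HSC pIpC replicate 1 and 3, to 697 and 655 without MPP PBS replicate 1 and 2, and to 642, 641 and 645 without MPP pIpC replicate 1, 2 and 3. Of 23 named genes 17 passed with each library left out. Ccnd1, Clec9a, Flt3, Mki67, Procr and Trem3 missed the threshold in fits without LT-HSC PBS replicate 1, 2 or 3 (adjusted p up to 0.141, 0.0618 and 0.499), LT-HSC pIpC replicate 1, 2 or 3 (0.113, 0.0797 and 0.112), MPP PBS replicate 1, 2 or 3 (0.0927, 0.0886 and 0.0952) or MPP pIpC replicate 1, 2 or 3 (0.106, 0.392 and 0.103).

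Between Lin and LT-HSC the pIpC effect differed for 2517 genes, 1581 more positive and 936 more negative in Lin. Ly6a again moved in opposite directions (3.85 ± 0.44, adjusted p = 1.03e-05), and Procr (4.94 ± 0.95), Flt3 (2.21 ± 0.61), Cd34 (3.37 ± 1.03) and Cdkn1c (6.15 ± 1.66), each lower after pIpC in LT-HSC, had a more positive effect in Lin. Of these, 3 genes had few counts over the Lin libraries after PBS and pIpC. Procr had 17 and 32, Cd34 26 and 78, and Cdkn1c 4 and 18, so their differences rest mainly on the fall in LT-HSC. Hlf (4.39 ± 0.43) and Gata3 (5.04 ± 0.54) were among 17 of 28 identity genes with a higher effect, 19 adjusted over the list alone, a call that held with an estimated correlation (adjusted p = 0.0447). Identity genes were low in Lin (mean log2 CPM -0.43 to 1.17 by library, against 6.42 to 6.87 in LT-HSC after PBS). The list median of the pIpC effect was -2.54 in LT-HSC and 0.36 in Lin, where the list was not called (adjusted p = 0.0714) and Gata3 rose (2.72 ± 0.40). Ifit1, an interferon-induced block to viral RNA, went from 21.8 to 72.9 CPM in Lin and from 27.2 to 15.5 in LT-HSC (2.54 ± 0.71, 0.0169). Oas1g (4.78 ± 0.51), Slfn8 (2.58 ± 0.46) and the nucleic acid sensor Zbp1 (2.65 ± 0.48) had a more positive effect in Lin. So did 22 of 51 interferon-stimulated genes, 28 adjusted over the list alone (median 1.27; adjusted p = 0.124 with an estimated correlation). Irf8 (3.06 ± 0.42), Iigp1 (3.66 ± 0.51), Gbp6 (5.36 ± 0.76) and Ifnar1 (1.52 ± 0.39) did too, and each fell in LT-HSC (-2.90 ± 0.32, -2.08 ± 0.35, -3.23 ± 0.54 and -1.29 ± 0.28). In Lin, Irf8, Gbp6 and Ifnar1 did not pass. Cd48 (-2.02 ± 0.50), Mki67 (-2.05 ± 0.50), Rad18 (-1.20 ± 0.34), Ttk (-2.47 ± 0.42) and Kif4 (-2.23 ± 0.38) had a lower effect in Lin. Mki67 went from 469.2 to 277.5 CPM in Lin, without passing there, and from 57.9 to 141.6 in LT-HSC. A lower effect was also called for 28 of 32 mitosis genes, 30 adjusted over the list alone (adjusted p = 0.0873 with an estimated correlation). The mean log2 CPM over this list after PBS was 6.8 to 7.719 in Lin and 4.365 to 4.813 in LT-HSC. Klf12 went in LT-HSC from 12.8 to 0.421 CPM, Clip3 from 9.06 to 0.479, Mill2 from 12.3 to 0.458 and Tgfb3 from 5.89 to 0.214, with 0 counts in Lin after PBS. Acmsd went from 0.512 to 5.65 CPM in LT-HSC and from 2.345 ± 3.803 CPM to 1 count in Lin (difference -9.99 ± 2.54). Phyhip and Susd2 had 0 counts in LT-HSC after PBS. Kit, Slamf1, Mcm5, Ccnd1, Cdk6, Cdkn1a, Myc, Irf7, Rev1 and Chek1 did not pass, with adjusted p from 0.0863 for Cdk6 to 1.0 for Slamf1. Without LT-HSC pIpC replicate 1 or 3, 1599 and 1611 genes differed, and 1252 in a fit of only the libraries compared. Of 27 named genes 18 passed with each library left out. Cd34 or Flt3 missed the threshold without Lin PBS replicate 2 (adjusted p up to 0.0602), Lin pIpC replicate 3 (0.0725), LT-HSC PBS replicate 2 (0.0570) or LT-HSC pIpC replicate 1 (0.0799), and Cd34 or Rad18 without LT-HSC pIpC replicate 3 (0.0738). Rad18 missed it without Lin PBS replicate 1 (0.0635), Acmsd without Lin PBS replicate 3 (0.0736), Ifit1 without LT-HSC PBS replicate 3 (0.0547), Cd34 and Mill2 without Lin pIpC replicate 1 (0.131 to 1.0), and Cdkn1c, Ifit1, Ifnar1, Rad18 and Tgfb3 without Lin pIpC replicate 2 (0.0501 to 1.0).

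After PBS, ST-HSC differed from LT-HSC in 460 genes, 363 higher and 97 lower (618 and 423 with DESeq2, 182 in all with limma voom and 104 in a fit of only the libraries compared). The replicate block gave 729, the block within treatment 870.0 and the TEC covariate 793. Cell division genes were higher in ST-HSC: of 32 mitosis genes 31 were higher, 32 adjusted over the list alone (median 2.20), a call that held with an estimated correlation (adjusted p = 0.00117). Kif4 was at 10.3 ± 3.10 CPM in LT-HSC and 67.3 ± 12.8 in ST-HSC (2.71 ± 0.28). Also higher were Ttk (2.98 ± 0.32), Prc1 (2.18 ± 0.27), Top2a (2.46 ± 0.31), Rrm2 (2.10 ± 0.37), Kifc1 (4.34 ± 0.86), Depdc1b (3.76 ± 0.45), separase Espl1 (3.40 ± 0.78), the centriole gene Stil (3.30 ± 0.62) and Fam83d (3.23 ± 0.38). Cd48 was higher (2.17 ± 0.37), as were Rad18 (1.30 ± 0.24), Rfwd3 (1.07 ± 0.25), cathepsin Ctsg (3.64 ± 0.92) and Slc9a9 (3.19 ± 0.72). Jchain, an immunoglobulin joining chain, had 18.4 ± 16.6 CPM in ST-HSC against 1 count in LT-HSC, and ranged from 0.567 to 33.4 CPM between ST-HSC PBS libraries. Sult1a1 (-2.72 ± 0.44), Ltb (-2.04 ± 0.37), Mllt3 (-1.54 ± 0.33) and Hlf (-1.31 ± 0.29) were lower, 4 of 28 identity genes or 9 adjusted over the list alone (adjusted p = 0.0525 with an estimated correlation). LT-HSC held more of the interferon-linked Gbp4 (-3.78 ± 0.82), Gbp9 (-2.94 ± 0.63), Zbp1 (-1.68 ± 0.34), Oas1g (-1.49 ± 0.35) and Ifi44 (-1.44 ± 0.36). Of 51 interferon-stimulated genes 3 were lower in ST-HSC, 9 adjusted over the list alone (median -0.46; adjusted p = 0.119 with an estimated correlation). Unc45b (-2.85 ± 0.56), Cyp26b1 (-3.97 ± 1.0), Gimap3 (-4.61 ± 0.99), Cd33 (-4.74 ± 1.16), Rab36 (-2.86 ± 0.77) and Amigo2 (-2.84 ± 0.78) were lower as well. Of 31 named genes 17 passed with each library left out. Of the others 7, 3 and 7 missed the threshold without LT-HSC PBS replicate 1, 2 and 3 and 7, 8 and 10 without ST-HSC PBS replicate 1, 2 and 3 (adjusted p up to 0.159), among them Cd33, Ctsg, Gbp4, Gbp9, Hlf, Ifi44, Mllt3, Oas1g and Rfwd3.

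MPP differed from LT-HSC after PBS in 1439 genes, 799 higher and 640 lower (922 in all without MPP PBS replicate 2 and 656 in a fit of only the libraries compared). Multipotent and lymphoid-myeloid priming genes were higher for 16 of 20, 18 adjusted over the list alone (median 4.41): Flt3, the receptor that defines these progenitors, was 654 ± 236 CPM in MPP against 22.5 ± 11 (4.86 ± 0.49), with Satb1 (4.64 ± 0.32) and Irf8 (3.09 ± 0.31). The DNA polymerase of antigen receptor joining, Dntt, was 488 ± 255 against 1.54 ± 1.45 CPM (8.22 ± 0.92). Sema3d (621-fold, counting interval 212 to 3014), Cd300lb (482-fold, counting interval 133 to 3992), Rag2 (254-fold, counting interval 86.4 to 1235), Ccr9 (208-fold, counting interval 70.7 to 1011) and Tnfsf8 (252-fold, counting interval 85.7 to 1224) were near 0 in LT-HSC, as were Gcsam (8.31 ± 1.04) and Slc18a1 (7.96 ± 1.03). Ttk (2.67 ± 0.31), Ect2 (3.33 ± 0.40), Rad18 (1.08 ± 0.24), Rfwd3 (1.07 ± 0.25) and the dendritic integrin Itgax (6.08 ± 1.0) were higher, and Zbp1 (-1.73 ± 0.34) lower. Identity genes were lower for 18 of 28 (23 adjusted over the list alone), with Tgm2 (-5.24 ± 0.44), Sult1a1 (-6.23 ± 0.53) and Trim47 (-3.43 ± 0.35). Platelet-lineage genes were lower for 14 of 18, the same number alone, with Vwf (-5.32 ± 0.54), Itgb3 (-3.96 ± 0.42), Gp1bb (-6.32 ± 0.73) and Cavin2 (-8.35 ± 1.11). The mitosis, priming, identity and platelet-lineage lists held with an estimated correlation (adjusted p = 0.00577, 3.91e-05, 4.06e-04 and 6.97e-04). Evc2, Evc, Gkn3, Dusp26, Tm4sf1 and Smpdl3b had 0 counts in MPP, which puts them at least 534-, 251-, 164-, 129.6-, 135- and 171-fold lower, and Runx1t1 had 2 counts (665-fold, counting interval 184 to 5492). All 31 named genes passed with each of the 6 libraries left out (highest adjusted p = 0.0407).

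Lin differed from LT-HSC after PBS in 8854 genes, 4029 higher and 4825 lower (5619 in all in a fit of only the libraries compared); the median of all genes lay at -0.19 here, or -0.088 with DESeq2-type size factors, and at -0.16 for pIpC in LT-HSC. Mature neutrophil genes were higher in Lin. Cd177, Lrg1, Itgb2l, Slfn4, Fcnb, C5ar1 and Olfm4 had 0 counts in LT-HSC and were at least 268600.0-, 70110.0-, 63680.0-, 57010.0-, 44830.0-, 36740.0- and 26360.0-fold higher in Lin. The gelatinase Mmp9 had 1 count against 4881 ± 2835 CPM. Ly6g (59830.0-fold, counting interval 16560.0 to 494100.0), Pglyrp1 (7.88 ± 0.69) and Padi4 (3.98 ± 0.38) were among 20 of 20 neutrophil genes that were higher, as many adjusted over the list alone (adjusted p = 0.398 with an estimated correlation). With 0 counts in Lin, the HSC regulator Mecom and Myct1, Nwd1, Trpc6, Fhl1, Lhcgr and Casp12 were at least 1530.0-, 2580.0-, 1185-, 957-, 934-, 769- and 729-fold lower. Robo4, at 0 counts in Lin, was at least 625-fold lower. Hlf (-5.55 ± 0.35) and Trim47 (-6.99 ± 0.43) were lower and Irf8 (4.13 ± 0.32) higher. Lower too were 27 of 28 identity genes, the same number adjusted over the list alone, a call that held with an estimated correlation (adjusted p = 0.0137). Growth genes were lower in Lin: Rpl15 (-1.99 ± 0.23) and Rpl14 (-2.29 ± 0.29) among 43 of 47 ribosomal protein genes, 44 adjusted over the list alone. Rrp9 (-3.26 ± 0.24) and Wdr12 (-3.51 ± 0.30) were lower too, among 23 of 28 ribosome biogenesis genes, the same number alone (adjusted p = 0.457 and 0.240 with an estimated correlation). Mitosis genes such as Birc5 (3.02 ± 0.30) and Kif4 (2.88 ± 0.29) were higher for 32 of 32, over all genes and adjusted over the list alone (adjusted p = 0.206 with an estimated correlation). All 28 named genes passed with each library left out (highest adjusted p = 8.33e-04).

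**Figure D3:**
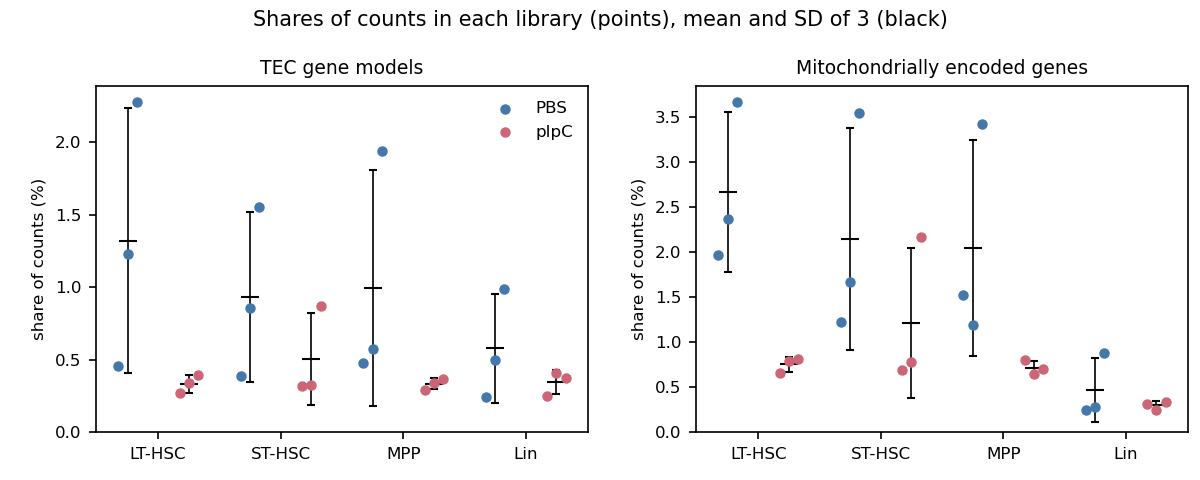
Share of counts on TEC gene models and on mitochondrially encoded genes, in %, for each library by cell type and treatment; points are libraries and black marks the mean ± SD of 3. Both shares were higher in LT-HSC after PBS (TEC 0.456 to 2.28%, mitochondrial 1.97 to 3.67%) than after pIpC.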

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

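The tests of splits other than those of the LT-HSC comparison, and the test against abundance-matched lists, were set before their results were seen. The other tests of explanations in this part were chosen after. The differences of effect, their list tests and the fits with a library left out were fixed before the data were examined.

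The effect of pIpC differed from LT-HSC by a test of the difference itself in ST-HSC, MPP and Lin, for 123, 1046 and 2517 genes. In ST-HSC the list medians of the difference were -1.64 for mitosis, -1.33 for replication licensing, -0.98 for replication elongation and -0.42 for repriming and translesion synthesis. They were 1.54 for LT-HSC identity, 1.04 for multipotent priming (2 of 20 genes higher, adjusted p = 0.129 with an estimated correlation) and 0.49 for type I interferon-stimulated genes. Of these lists mitosis and identity alone held with an estimated correlation. Among single genes Cd33 differed by 9.45, Mgst2 by 4.47, Cdh23 by 4.15 and Dok3 by 3.97, while Gstp3 differed by -5.81, Hexim2 by -3.96, Ccne1 by -3.61 and Bub1 by -3.03. Cd33 went from 5.06 to 0.0925 CPM in LT-HSC and from 0.139 to 2.92 CPM in ST-HSC, where pIpC replicate 1 held 8.12 CPM and the others 0.162 and 0.472. Mgst2 went from 20.5 to 0.536 CPM in LT-HSC and from 4.00 to 2.37 in ST-HSC.

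In MPP the medians of the difference were -1.77 for mitosis, -0.38 for repriming, 1.66 for LT-HSC identity, 1.61 for interferon-inducible GTPases, 2.32 for multipotent priming and 0.65 for interferon-stimulated genes. Of these lists identity and multipotent priming alone held with an estimated correlation. The repriming call was lost with an estimated correlation (adjusted p = 0.323) and without LT-HSC PBS replicate 1 or 3, LT-HSC pIpC replicate 2 or MPP PBS replicate 3 (adjusted p = 0.0773, 0.0775, 0.0529 and 0.0971). Ly6a differed by 3.64, Cd48 by -2.84, Flt3 by 2.33, Procr by 3.10, Mki67 by -1.76 and Ccnd1 by 2.58. Smpdl3b (10.07), Btla (8.65), Clec9a (7.36), Trem3 (7.33), Susd2 (-11.14), Add2 (-8.54) and Col5a1 (-7.99) were among the largest fitted differences. Those of Smpdl3b, Btla and Susd2 depend on the prior count, as 1 group had 0 counts. Smpdl3b went from 5.09 to 0.392 CPM in LT-HSC and from 0 to 0.381 in MPP. Btla went from 1.69 to 0 in LT-HSC, where PBS replicate 3 held 4.62 CPM and the others 0.209 and 0.226, and from 27.2 to 30.9 in MPP. Susd2 went from 0 to 10.4 in LT-HSC and from 0.632 to 0.651 in MPP.

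In Lin the medians of the difference were -2.07 for mitosis, 3.68 for LT-HSC identity and 1.27 for interferon-stimulated genes. The identity median of the pIpC effect itself was -2.54 in LT-HSC and 0.36 in Lin, where identity genes were low (mean log2 CPM -0.43 to 1.17 by library) and Gata3 rose. The medians of the difference were 2.23 for interferon-inducible GTPases (16 of 24 genes higher, adjusted p = 0.0607 with an estimated correlation) and 2.47 for multipotent priming (9 of 20 higher, adjusted p = 0.124 with an estimated correlation). Of the lists named here for Lin identity alone held with an estimated correlation. Ly6a differed by 3.85, Cd48 by -2.02, Flt3 by 2.21, Procr by 4.94, Cd34 by 3.37, Mki67 by -2.05, Cdkn1c by 6.15, Ifit1 by 2.54, Ifnar1 by 1.52 and Rad18 by -1.20. Procr, Cd34 and Cdkn1c had 17, 26 and 4 counts over the Lin libraries after PBS. Among the largest fitted differences, those of Klf12 (11.45), Clip3 (11.38), Mill2 (10.81), Tgfb3 (10.78), Phyhip (-11.20), Susd2 (-10.78) and Acmsd (-9.99) depend on the prior count, since a group had 0 counts or, for Acmsd, 1 count. After PBS and pIpC in Lin, Klf12 went from 0 to 0.420 CPM, Clip3 from 0 to 0.648, Mill2 from 0 to 0.310, Tgfb3 from 0 to 0.289 and Phyhip from 5.22 to 0.330. PBS replicate 3 carried that Phyhip mean, at 14.5 CPM against 0.365 and 0.846.

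Regrouping the libraries of these comparisons gave as many differing genes as the real labels in 15, 14 and 9 of 100 splits for ST-HSC, MPP and Lin, with up to 6662, 6403 and 4692 genes against 123, 1046 and 2517, so this count does not exclude chance. The larger splits point to a structure of the samples. Of the other splits as large (14, 13 and 8), 13, 13 and 8 kept the LT-HSC PBS and pIpC libraries apart, which carries the LT-HSC response into the difference. Splits that mixed them reached at most 492, 2 and 27 genes. For the average over cell types 1 of 100 splits, the real one, called as many (6285 against at most 4608). That share argues against chance only for the case of no effect in any cell type. The count follows the LT-HSC grouping as well: the 15 other splits that kept LT-HSC apart reached up to 4608 genes and the 84 that mixed it at most 1. Those 15 are too few for a share under 0.05, so chance is not excluded beyond the LT-HSC grouping. The count does not by itself show an effect shared by the 4 cell types. For pIpC in LT-HSC, ST-HSC and MPP and for ST-HSC, MPP and Lin against LT-HSC after PBS, 10 splits are too few for a share under 0.05. The real labels called 6190, 316, 30, 460, 1439 and 8854 genes, 1 split each. The highest other split called 0, 2, 0, 41, 1 and 17. For Lin 2 of 10 splits called as many, again too few to judge. The split that set PBS replicate 1 with pIpC replicates 1 and 3 against the rest called 869 genes against the real 100, which points to a structure of the samples other than treatment.

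The first pattern weighed was the fall of LT-HSC identity genes and the rise of erythroid genes in LT-HSC after pIpC. A bias by GC content or gene length is argued against, since with offsets the identity median was -2.44. For a swap with pIpC libraries of another cell type, 0 of the 9 other pIpC libraries reached the identity level of the LT-HSC PBS libraries. That cannot decide on a swap, since pIpC itself may lower the list. After PBS the mean log2 CPM over the identity list was 6.42 to 6.87 in LT-HSC and 5.42 to 5.82 in ST-HSC. After pIpC the order was the other way, with 3.76 to 4.35 in LT-HSC and 4.39 to 4.54 in ST-HSC. Hemoglobin-rich red cells in the gate are argued against by a hemoglobin share of at most 6.19e-04% after pIpC, below the lowest PBS library (9.46e-04%). Early erythroid progenitors that enter the gate, for instance where pIpC changes the surface markers used for sorting, remain open and could explain part of it: 8 of 21 erythroid genes were higher, and no value separates added cells from a change within LT-HSC, or from a biological effect of pIpC, which was not tested apart.

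The second pattern was the rise of ribosomal protein and oxidative phosphorylation lists in the 4 cell types, 8 list calls that were all lost with an estimated correlation. GC content or gene length is argued against as the whole cause, as 8 of 8 calls held with offsets. The medians with offsets were not compared. Background reads tracked by the TEC share are argued against as the whole cause in ST-HSC and MPP, where 4 of 4 calls held with that share as a covariate but the ribosomal protein medians went from 0.49 to 0.36 and 0.46 to 0.19 and the oxidative phosphorylation medians from 0.54 to 0.36 and 0.55 to 0.31, so they may account for part of the rise there too. In LT-HSC and Lin 2 of 4 calls held, among them oxidative phosphorylation in LT-HSC with a median that went from 1.07 to 0.61, and 2 were lost: the ribosomal protein median in LT-HSC went from 0.64 to 0.24 (quartiles of members 0.070 to 0.42; adjusted p = 6.38e-04 and 0.0860) and the oxidative phosphorylation median in Lin from 0.25 to 0.15 (0.039 to 0.24; 0.00184 and 0.0820), so the calls ended with smaller changes. A trend of fold change with abundance stays open: 3 of 8 medians lay in the upper 2.5% of 10000 abundance-matched random lists. They were oxidative phosphorylation in LT-HSC and ST-HSC (percentiles 99.9 and 99.6) and ribosomal proteins in Lin (99.85). Ribosomal protein medians in LT-HSC, ST-HSC and MPP lay at percentiles 67.8, 86.8 and 11.6, within the range of equally abundant genes. Oxidative phosphorylation in MPP and Lin lay at 95.6 and 95.3. A growth response to pIpC was not tested apart from these.

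The third pattern was the more positive effect of pIpC on interferon-stimulated genes in ST-HSC, MPP and Lin than in LT-HSC (list median -0.25 in LT-HSC and 0.23 in ST-HSC), a set of calls with adjusted p = 0.253, 0.301 and 0.124 with an estimated correlation. In ST-HSC the median difference to LT-HSC was -0.46 after PBS and 0.0071 after pIpC. For each gene the difference of effect is the change between these differences. They therefore cannot tell a higher starting level in LT-HSC from a different response. In MPP the medians were -0.28 and 0.51, where the first call missed the threshold without LT-HSC PBS replicate 3 (adjusted p = 0.0653). In Lin they were 0.23 and 1.48. For MPP the medians cannot tell start from response. In Lin LT-HSC had no higher median start, which argues against it as the whole cause. Background tracked by the TEC share and GC content or length are argued against as the whole cause, as 3 of 3 preset-correlation calls held under each. The size of the differences under them was not compared, so either may account for part. The time since pIpC, which the labels do not give, and a true difference between cell types remain as open, untested explanations, each of which might fit these values.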

How the results depend on the processing

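Replicate numbers 1 and 2 only, GC and length offsets, the TEC share as a covariate and protein-coding genes over 5 CPM are tests chosen after the results were seen; the other alternatives were fixed before the data were examined.

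Named genes that passed in the main fit or in the alternative kept their direction. Of 7539 values of named genes under an alternative, 6735 kept their side of the threshold. These include values that passed in neither fit and changed sign by less than their standard error. Of the rest 739 no longer passed, 52 newly passed, and 13 that passed in neither changed sign by more than their standard error. With a pass in either fit, 0 reversed. Of 2892 values of called lists, 2512 were kept, 379 lost the call and 1 reversed. GC and length offsets and the stricter filter kept 11 of 11 gene counts within 1.5 times. Except where a smaller set of genes or libraries was used, the cause of the following changes was not tested.

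Counts for pIpC in LT-HSC, ST-HSC, MPP and Lin were 6190, 316, 30 and 100. With a test against a fold of 1.5 they were 3910.0, 106, 2 and 51, a stricter question by construction. With replicate numbers 1 and 2 only, fewer libraries gave 3772, 88, 0 and 18. For the 0 in MPP, edgeR found 967 genes at an unadjusted p under 0.05, and with all libraries DESeq2 and limma voom called 725 and 2487. The replicate block gave 1039 in ST-HSC and 932 in MPP, and changed no other call in these 4 comparisons by over 1.5 times. DESeq2 gave 1287 in ST-HSC, 725 in MPP and 345 in Lin, and voom 2202, 2487 and 48. A fit of only the libraries compared gave 447 in MPP and 4 in Lin. In MPP, DESeq2-type size factors gave 18 and no filter 13. The TEC covariate gave 522 in ST-HSC, and protein-coding genes over 5 CPM gave 490.0 in ST-HSC and 75 in MPP. For the average (6285) the fold test gave 1192 and the TEC covariate 2582.

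For differences from LT-HSC in ST-HSC, MPP and Lin (123, 1046 and 2517) the fold test gave 15, 610.0 and 1565 and replicates 1 and 2 only gave 0, 324 and 1043. For that 0 edgeR found 1307 genes at an unadjusted p under 0.05, and with all libraries DESeq2 and voom called 694 and 234. The block gave 371 in ST-HSC, the block within treatment 526 in ST-HSC and 1709 in MPP, DESeq2 694 and 1711, voom 234 and 2662, and the TEC covariate 332 and 1609. Coding genes over 5 CPM gave 209 in ST-HSC, and only the libraries compared 1252 in Lin. For ST-HSC, MPP and Lin against LT-HSC after PBS (460, 1439 and 8854) only the libraries compared gave 104, 656 and 5619, replicates 1 and 2 only gave 133 and 793 in ST-HSC and MPP, and the fold test 249 and 912. In ST-HSC the block gave 729, the block within treatment 870.0, DESeq2 1041, voom 182 and the TEC covariate 793.

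With each library left out, counts ranged from 4112 to 6562 in LT-HSC, 89 to 362 in ST-HSC, 1 to 19 in MPP, 55 to 282 in Lin and 2836 to 5191 for the average. Differences from LT-HSC ranged from 17 to 200, 535 to 1021 and 1599 to 2683, and comparisons after PBS from 344 to 471, 922 to 1289 and 7837 to 8691. A pair of libraries left in a group is assumed to vary like the other groups. Called lists ranged over 18 to 21, 7 to 14, 18 to 20, 9 to 20 and 18 to 20 for pIpC in LT-HSC, ST-HSC, MPP, Lin and the average. They ranged over 18 to 21, 14 to 20 and 16 to 20 for the differences, and 16 to 18, 17 to 22 and 15 to 19 after PBS. The neutrophil list in ST-HSC reversed without ST-HSC pIpC replicate 1 (adjusted p = 0.0180), with adjusted p from 1.42e-05 to 0.196 over the 6 fits.

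With an estimated correlation 1, 0, 0 and 2 lists were called for pIpC in LT-HSC, ST-HSC, MPP and Lin, and 0 for the average. It called 2, 2 and 1 for the differences and 1, 5 and 1 after PBS. This is against 19, 12, 20, 12, 21, 20, 17, 18, 17, 17 and 16 with the preset correlation. Beside the 0 in ST-HSC and MPP, fry called 2 and 3, and beside the 0 for the average it called 27. It called 5 in Lin and 25 for Lin against LT-HSC after PBS.

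Primpol did not pass in any alternative, and its log2 fold change kept its sign in 55 of 64 values. In LT-HSC it was 0.015 without a filter and 0.24 with the TEC covariate, in ST-HSC 0.0075 and 0.066. It was 0.022 in ST-HSC without PBS replicate 3. In Lin it was 0.033 without PBS replicate 3, 0.083 with replicates 1 and 2 only, 0.031 with offsets and 0.033 with the TEC covariate. With each library left out it ranged from -0.20 to -0.03 in LT-HSC, -0.20 to 0.02 in ST-HSC, -0.41 to -0.04 in MPP and -0.17 to 0.03 in Lin, within its 95% intervals.

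Depth was 13178899 to 54891041 counts, which limits calls of genes near the floor of 3 counts. In simulated data with 200 changed genes, 8 to 14 of 100 genes changed 2-fold were recovered.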

Other observations

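No further hypothesis was tested in this part; the values describe libraries and were looked at after the results were seen.

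ST-HSC pIpC replicate 1 had a mean log2 CPM of 5.51 over the neutrophil list, against -1.82 to 1.18 in the other 5 ST-HSC libraries. Lin PBS replicate 3 held 1.92% hemoglobin counts and 98.2 CPM of Sox6, against 1.64 and 2.60 CPM in the other Lin PBS libraries, and a mean log2 CPM of 8.73 over the erythroid list against 4.35 and 3.38. Jchain was at 0.567, 33.4 and 21.4 CPM in ST-HSC PBS replicates 1, 2 and 3.

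LT-HSC libraries after PBS were less alike (Pearson r of log2 CPM across genes 0.864 to 0.913) than after pIpC (0.984 to 0.986). The mitochondrial share was 2.17% in ST-HSC pIpC replicate 3, with 0.691 and 0.778% in the other ST-HSC pIpC libraries. Among TEC gene models 0 passed for pIpC in ST-HSC, MPP or Lin alone by edgeR, while 29 were higher and 460.0 lower in the average. The first principal component held 55.7% of the variance and set Lin apart, and the second held 11.4%, with LT-HSC libraries at -139 to -29.5 after PBS and 72.2 to 108 after pIpC. The log2 fold change after pIpC rose with abundance across genes (Spearman rho 0.375 in LT-HSC, 0.343 in ST-HSC, 0.450 in MPP and 0.168 in Lin).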
